A study of Mus musculus with 6 samples.

How the data were processed

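RNA of CD4 T cells from OT-II transgenic mice was measured on 1-colour Affymetrix whole-transcript arrays, 3 from cells in control medium and 3 from cells in medium with 1% of the normal arginine (12 uM), after 72 hours with antigen-presenting cells and an ovalbumin peptide. The deposited values were log2 expression values per probe set, normalised between arrays by the authors. Their processing notes name the oligo package. Its version, the background correction, the normalization method, the summarization and the log base are not given in the sources used here. The base was taken as 2 from the range of the values (0.956 to 12.41) and the type of array. The sorted values of the 6 arrays differed by at most 0.199, so the arrays had been brought to nearly the same distribution. The files used here held no detection calls and no scanner signals, so no probe set was tested against its background. Arrays have no sequencing depth, and their number limits the precision.

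Of 41345 probe sets, 23521 carried exactly 1 gene symbol in the table of the array's probes, 1814 carried several and 16010 none. The first class entered the comparison, and the brightest probe set by mean over all arrays stood for its gene, which gave 22180 genes. The dimmest of these, a share of 0.333 by mean level (7393 genes, limit 2.48), were left out, and 14787 genes were tested. Cd247, on the list of genes to be named whatever their result, was not analysed here.

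The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values as deposited, group only, two-sided, 4 residual and 3.69 prior degrees of freedom). P values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05 on the adjusted p. Values are given as mean ± SD over the 3 arrays of a group, and changes as low arginine minus control on the log2 scale. Gene lists, 34 in all, were tested with limma's camera, with its preset correlation of 0.01 between genes and adjustment over the lists. They cover amino acid supply and stress, energy and lipid metabolism, ribosomes, the cell cycle, interferon, T cell states, and markers of other cell types that the co-culture could leave behind. Of 917 list members, 797 were matched to a gene of the probe table by symbol, or by older symbols through a RefSeq table of the mouse assembly GRCm38.p6. Within each list, members past the threshold were also counted with p adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, were run beside it. With an estimated correlation camera also takes only the 4 residual degrees of freedom, which weakens it whatever the correlation. Figures were drawn with matplotlib 3.10.9.

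The groups, the test, the lists, the alternatives and the rule for the genes to be named were fixed before the data were examined. The rule took the 6 largest rises and the 6 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted genes and receptor segments. It took the 3 members with the largest change in the direction of each list called by camera. It took 20 genes whatever their result, among them Slc7a1, Ass1, Asl, Arg1, Atf4, Cd3e, Cd4, Myc, Il2, Foxp3 and Mki67, and from each list of other cell types the member with the largest change and the brightest one. Further genes were named after their values were seen, where a list had 5 or fewer changed members in 1 direction, and 6 further lists were written after the largest changes had been seen.

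On simulated data of the same size (14787 genes, 200 of them changed), limma recovered 14% of changes of 0.5 on the log2 scale, 90% of 1, 100% of 2 and 98% of 3, with 10 false calls. With no gene changed it called 0 genes and camera 0 lists. The simulated genes were drawn independently of each other, so this does not measure camera's false calls among correlated genes. In the real data the estimated correlation reached 0.898 over the mitosis list. The alternatives were quantile normalization, centring each array on its median or its 75th percentile, no filter on dim genes, leaving out a share of 0.5 as dim, the mean of a gene's probe sets, a trended and robust prior in eBayes, array weights, the replicate number as a block, and leaving out each array in turn.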

Results

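Gene expression was measured in CD4 T cells of OT-II mice, whose transgenic T cell receptor recognises a peptide of ovalbumin. The cells were stimulated for 72 hours with antigen-presenting cells and that peptide. They were kept either in control medium or in medium holding 1% of the normal arginine (12 uM), and CD4 cells were purified again before the RNA was taken. Each group had 3 arrays, and the description of the study names 6 mice. The labels do not say whether arrays of the same replicate number share mice. The main fit took all arrays as unpaired, although Y-linked levels matched by number. The comparison asks which genes differ between stimulated CD4 T cells short of arginine and those with a normal supply. Array values ran from 0.956 to 12.41 on the log2 scale, and the medians of the 6 arrays lay between 2.97 and 3.03. The small number of arrays limits the precision of every value.

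By limma's camera with its preset correlation between genes, amino acid transporters (7 of 21 rose) and Atf4 targets of the amino acid response (9 of 23 rose) shifted up in low arginine. Glycolysis (17 of 18 fell), cholesterol synthesis (17 of 19) and mitosis genes (33 of 35) shifted down. With an estimated correlation none of these 5 lists was called (adjusted p = 0.147 to 0.481). The largest rise was in Il2, the T cell growth factor, from 2.32 ± 0.28 (SD, n = 3) to 6.19 ± 1.09 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0046). Its control level lay under 2.48, the limit used for dim genes, so the size of this rise is uncertain. Cth, an enzyme of cysteine synthesis, rose by 3.26 (adjusted p = 0.00877), Trat1, an adaptor of the T cell receptor complex, by 2.93 (6.02e-04), and Tnfrsf19 by 2.76 (6.53e-04). Ermn rose by 2.71 (adjusted p = 3.24e-04) and Glce, an enzyme of heparan sulfate synthesis, by 2.28 (3.45e-04). The second probe set of Glce rose less, by 0.76.

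The largest falls were in genes of lipid desaturation, hypoxia, glucose uptake and metal binding. Fads2, a fatty acid desaturase, fell by 4.26 on the log2 scale (adjusted p = 0.0036) and Scd1, the stearoyl-CoA desaturase, by 3.93 (8.26e-04). Bnip3, a mitochondrial protein induced by hypoxia, went from 7.40 ± 0.19 to 3.29 ± 0.45 (SD, n = 3; limma adjusted p = 3.24e-04). Slc2a3, a glucose transporter, went from 9.36 ± 0.14 to 5.34 ± 0.21 (limma adjusted p = 6.37e-05). The metallothioneins Mt1 and Mt2 fell by 3.99 (adjusted p = 3.24e-04) and 3.84 (0.00103). The low arginine levels of Fads2, Scd1 and Bnip3 lay within 1 log2 of the dim limit, so the sizes of these falls are uncertain as well. All 12 of these largest rises and falls stayed past the threshold in every alternative tried.

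Of 14787 genes tested, 1799 (12.2%) changed at an adjusted p below 0.05. Of these, 767 were higher and 1032 lower in low arginine, and 580 changed at least 2-fold. With each array centred on its 75th percentile, the split was 535 higher and 1190 lower. The median fold was 1.60 among the genes that rose and 1.83 among those that fell. At an unadjusted p below 0.05 there were 4032 genes. The groups did not overlap for any of the 1799 genes, nor for 4766 (32.2%) of all genes tested, where chance gives 10%. The first principal component took 60.5% of the variance and separated the groups, and the second took 22.5% and set control replicate 1 (score 35.2) apart from the other controls (-8.53 and -22.3). Without control replicate 1 the count was 3325 (1626 higher, 1699 lower), and without control replicate 2 it was 500 (162 higher, 338 lower). Without low arginine replicate 1, 2 or 3 it was 995 (332 and 663), 509 (161 and 348) or 592 (200 and 392). The count of genes changed at least 2-fold was 323 without control replicate 2 and 331 or 367 without low arginine replicate 2 or 3. With array weights, 5514 genes passed (2777 higher, 2737 lower).

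**Figure D1:**
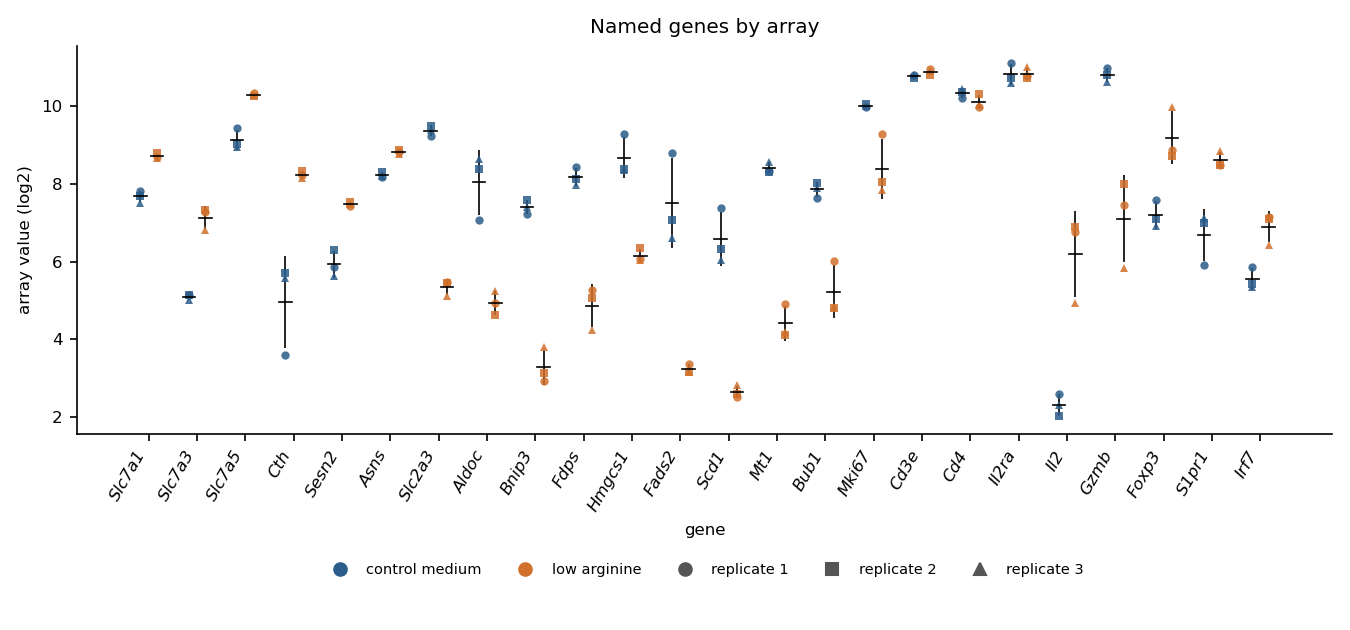
Array values (log2, vertical axis) of 24 named genes (horizontal axis) in control medium (blue) and low arginine (orange); each point is 1 array, the marker gives the replicate number, the short line the mean and the vertical line the SD (n = 3). Slc2a3, Bnip3, Fads2 and Scd1 lay lower in every low arginine array than in any control array, while Cd3e, Cd4 and Il2ra overlapped between the groups.

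By limma's camera, 11 of the 34 gene lists shifted up and 8 shifted down. None of these calls held when camera estimated the correlation between genes (lowest adjusted p = 0.147). In that setting 3 lists lay at an unadjusted p below 0.05. The p53 list lost its call there (adjusted p = 0.481) at an estimated correlation of 0.0087, below the preset 0.01. A call lost there need not reflect correlation between genes. Fry passed 9 lists. The 2 up were amino acid transporters and p53 targets. The 7 down were glycolysis, cholesterol synthesis, mitosis, histones, Th1 genes, CD8 and NK markers and plasma cell markers. The Atf4 targets did not pass fry (adjusted p = 0.0517). Lists shifted up numbered 7 without control replicate 1, 7 without low arginine replicate 2 and 5 with array weights. Where 5 or fewer members of a list passed in 1 direction, all of them are named, and members named without a log2 change of their own were chosen after their values were seen.

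**Figure D2:**
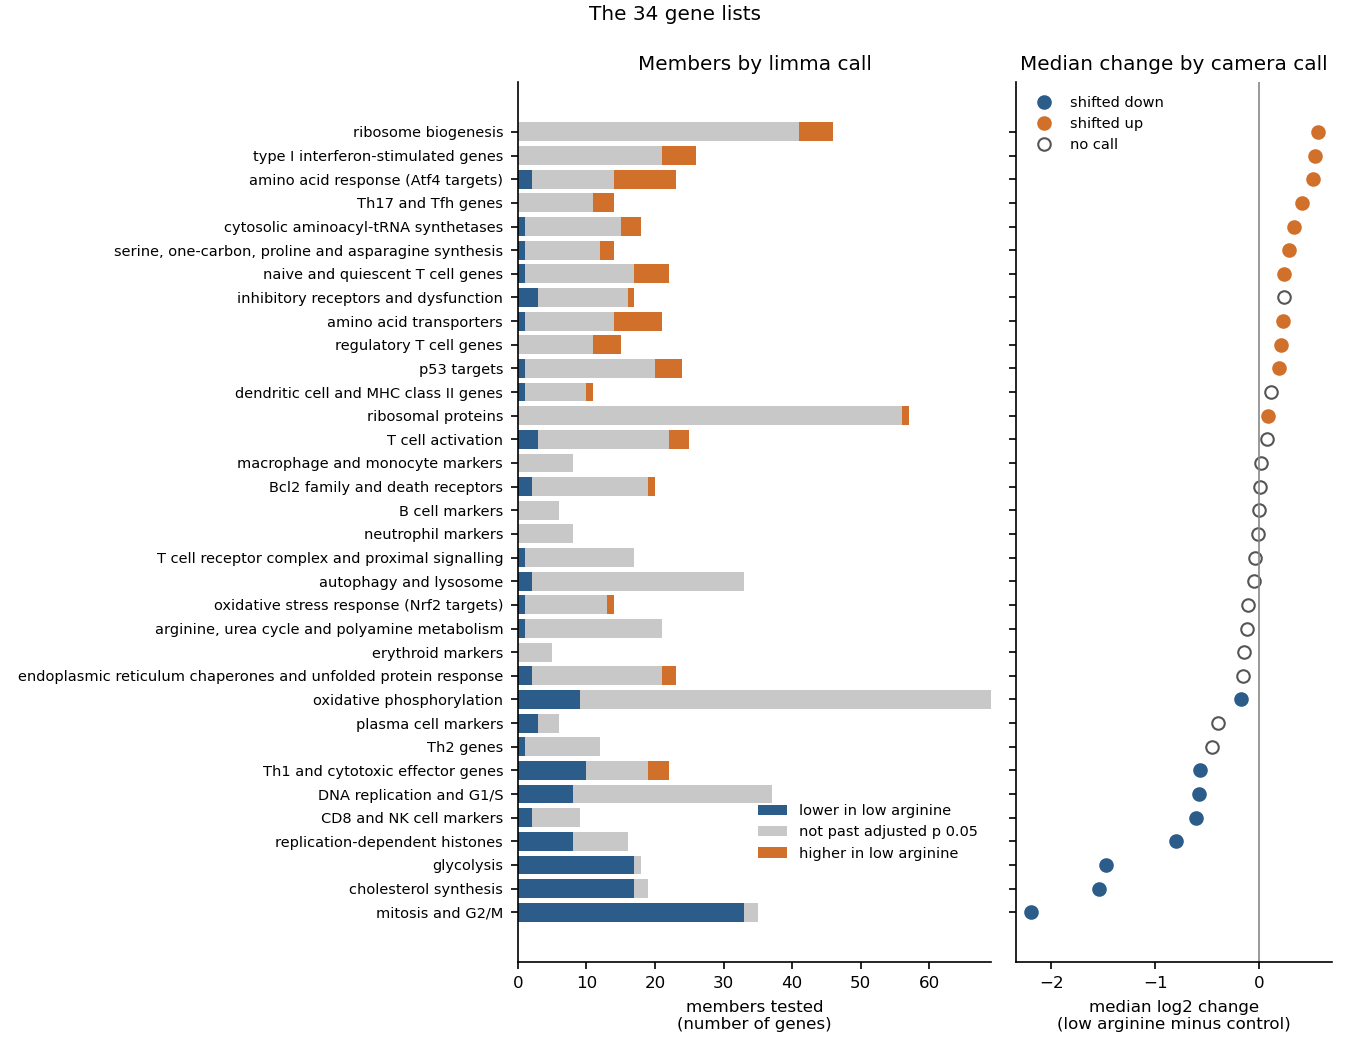
Left, the members tested of each gene list (number of genes), divided into those lower, not past the threshold and higher in low arginine; right, the median log2 change of each list, filled where camera called a shift with its preset correlation. The mitosis list had the largest median fall (-2.20) and 33 of its 35 members passed the threshold.

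The amino acid response, driven by the transcription factor Atf4, shifted up. Cth rose by 3.26 on the log2 scale (adjusted p = 0.00877) and Sesn2, an inhibitor of mTORC1, by 1.55 (0.00318). The stress gene Nupr1 rose from 6.18 ± 0.74 to 7.68 ± 0.21 (SD, n = 3; limma adjusted p = 0.0288). Chac1, which degrades glutathione, rose by 0.88 (adjusted p = 0.0121) and Asns, the asparagine synthetase, by 0.59 (0.0128). Of 23 members tested, 9 rose and 2 (Ddit4 and Stc2) fell, or 12 and 3 when adjusted over the list alone (median change 0.51, camera adjusted p = 1.99e-04, adjusted p = 0.481 with an estimated correlation). Atf4 itself changed by 0.14 (adjusted p = 0.583), Ddit3 by 0.51 (0.486) and Trib3 by 0.94 (0.0744). The median difference of control replicate 1 from the other controls over this list was -0.34. With array weights the list median was 0.31. Trib3 passed without control replicate 1, with a change of 0.58 (adjusted p = 0.0168), as it did with array weights (0.037), and without that array Ddit3 changed by -0.03 (0.901). Without low arginine replicate 2 the list had 5 rises, and the calls of Asns (adjusted p = 0.0661) and Chac1 (0.0589) ended, the latter also without control replicate 2 (0.0513). Nupr1 did not pass without low arginine replicate 1, 2 or 3 (adjusted p = 0.0687, 0.101 and 0.112). Ddit4 failed without control replicate 2 or low arginine replicate 1 or 3 (adjusted p = 0.0572 to 0.073), and Stc2 without any single array other than control replicate 1 (0.056 to 0.103).

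Amino acid transporters shifted up as well. Slc7a1, the main carrier of arginine and lysine, went from 7.67 ± 0.15 to 8.71 ± 0.06 (SD, n = 3), a log2 change of 1.04 (limma adjusted p = 0.00334). The cationic amino acid carrier Slc7a3 rose by 2.03 (adjusted p = 6.76e-04), the cystine carrier Slc7a11 by 1.33 (0.0137) and the leucine carrier Slc7a5 by 1.15 (0.00474). The other probe set of Slc7a11, dimmer, changed by 0.06. Of 21 members tested, 7 rose and 1 (Slc6a6, the taurine carrier) fell, the same counts when adjusted over the list alone (median 0.23, camera adjusted p = 0.0029, adjusted p = 0.481 with an estimated correlation). The median was 0.15 with no filter on dim genes and 0.35 with array weights. Without control replicate 2 or low arginine replicate 2 the list had 4 rises, and Slc7a11 did not pass (adjusted p = 0.0656 and 0.0662). Slc6a6 failed without control replicate 2 or any single low arginine array (adjusted p = 0.0526 to 0.075).

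Among the cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, Lars rose by 0.88 (adjusted p = 0.00484), Yars by 0.41 (0.0329) and Eprs by 0.41 (0.0438), while Qars fell. These were 3 rises and 1 fall among 18 members, or 6 and 1 when adjusted over the list alone (median 0.34, camera adjusted p = 0.0336, adjusted p = 0.481 with an estimated correlation). The list call ended without control replicate 3 (adjusted p = 0.104) or low arginine replicate 1 (0.0578) or 2 (0.0587), and with array weights (0.0619). The median was 0.18 without control replicate 3. There were 9 rises without control replicate 1 and 1 without any other single array, Yars (adjusted p = 0.0643 to 0.12) and Eprs (0.0823 to 0.16) being lost each time. Centred on the 75th percentile, Yars and Eprs did not pass (adjusted p = 0.0747 and 0.102), nor did Eprs after quantile normalization (0.0547) or median centring (0.066).

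Serine, one-carbon, proline and asparagine synthesis shifted up, led by the mitochondrial folate enzyme Aldh1l2, which rose by 1.41 (adjusted p = 0.00536), and Asns, which rose by 0.59 (0.0128). Got2 fell. That made 2 rises and 1 fall among 14 members, or 5 and 2 when adjusted over the list alone (median 0.29, camera adjusted p = 0.0466, adjusted p = 0.497 with an estimated correlation). The list call ended without control replicate 3 (adjusted p = 0.11) or low arginine replicate 1 (0.11) or 2 (0.07), with 0.5 of genes left out as dim (0.06) and with array weights (0.0976). There were 5 rises without control replicate 1 and 1 without low arginine replicate 2, where Asns failed (adjusted p = 0.0661). Got2 failed without control replicate 2 or any single low arginine array (adjusted p = 0.0543 to 0.0828). Asns also stands in the list of Atf4 targets.

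The genes of arginine metabolism itself were not called shifted. Ass1 and Asl, which make arginine from citrulline, changed by -0.05 (adjusted p = 0.864) and -0.59 (0.0657), and the arginase Arg1 by -0.04 (0.852). Of 21 members of the arginine, urea cycle and polyamine list, 1 passed, Oaz1, an inhibitor of polyamine synthesis that fell (list median -0.12, camera adjusted p = 0.227). Limma passed 0 members when adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p below 0.05, and fry gave the list an adjusted p of 0.172. Oaz1 did not pass without control replicate 2 or any single low arginine array (adjusted p = 0.0833 to 0.142). Without control replicate 1, 5 members rose and 3 fell. The list median was -0.05 without low arginine replicate 3 and -0.18 without low arginine replicate 2. Asl passed with array weights (adjusted p = 0.00903).

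Glycolysis fell nearly as a whole. Of 18 members tested, 17 fell, over all genes and when adjusted over the list alone, and only the lactate and pyruvate carrier Slc16a1 did not pass. Slc2a3 fell by 4.02 on the log2 scale (adjusted p = 6.37e-05). The aldolase Aldoc fell by 3.09 (adjusted p = 0.00474) and the lactate exporter Slc16a3 by 2.70 (9.32e-05). The median change of the list was -1.48 (camera adjusted p = 2.08e-19, adjusted p = 0.147 with an estimated correlation).

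Oxidative phosphorylation shifted down by less. The complex I subunit Ndufv3 fell by 1.03 (adjusted p = 0.00312), Cox7a2 of complex IV by 0.85 (0.00818) and Uqcrfs1 of complex III by 0.79 (0.00853). They were among 9 members of 69 that fell, or 11 when adjusted over the list alone (median -0.17, camera adjusted p = 1.99e-04, adjusted p = 0.59 with an estimated correlation). Control replicate 1 lay above the other controls over this list (median difference 0.34), and without it the list call ended (median -0.02, adjusted p = 0.111). The groups overlapped in their median deviations from the mean of all arrays. Control replicate 3, at -0.102, lay below low arginine replicates 1 and 2 (-0.076 and -0.051) and above low arginine replicate 3 (-0.114). Without control replicate 3 the median was -0.30, and with array weights -0.105. The count of falls was 3 without control replicate 2, low arginine replicate 1 or low arginine replicate 3, and 4 without low arginine replicate 2.

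Cholesterol synthesis fell. Of 19 members, 17 fell, over all genes and when adjusted over the list alone, and Hsd17b7 and Ebp did not pass. Fdps, the farnesyl diphosphate synthase, went from 8.17 ± 0.24 to 4.87 ± 0.55 (SD, n = 3; limma adjusted p = 8.5e-04). Hmgcs1, which makes HMG-CoA, fell by 2.52 (adjusted p = 0.00203) and Cyp51, the lanosterol demethylase, by 2.14 (0.00875). The median change was -1.54 (camera adjusted p = 9.13e-16, adjusted p = 0.448 with an estimated correlation). Over these genes control replicate 1 lay above the other controls (median difference 0.73). The count of falls was 10 without low arginine replicate 2 and 11 without low arginine replicate 3.

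Mitosis genes showed the largest shift of all lists. Cdc25c, a phosphatase that starts mitosis, fell by 2.79 (adjusted p = 0.00107), the checkpoint kinase Bub1 by 2.63 (0.00397) and Cdc25b by 2.60 (0.00474). The proliferation marker Mki67 went from 10.0 ± 0.04 to 8.38 ± 0.78 (SD, n = 3; limma adjusted p = 0.0228). Of 35 members, 33 fell, or 34 when adjusted over the list alone (median -2.20, camera adjusted p = 5.93e-23, adjusted p = 0.481 with an estimated correlation). Low arginine replicate 1 stood apart from the other low arginine arrays, its median deviation from the mean of all arrays being -0.08 against -1.39 and -1.65, with 1.04 to 1.15 in the controls. The count of falls was 9 without control replicate 2, 6 without low arginine replicate 2 and 16 without low arginine replicate 3. Mki67 did not pass without control replicate 2 or 3 or low arginine replicate 2 or 3 (adjusted p = 0.0554 to 0.0967).

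DNA replication genes and histones shifted down too. E2f2, a transcription factor of S phase entry, fell by 1.48 (adjusted p = 0.00974), the thymidine kinase Tk1 by 1.38 (0.0197) and the cyclin Ccne1 by 1.19 (0.0278). Of 37 replication members 8 fell, or 16 when adjusted over the list alone (median -0.58, camera adjusted p = 1.44e-08, adjusted p = 0.562 with an estimated correlation). Among replication-dependent histones, H2bc12 fell by 2.50 (adjusted p = 0.0117), the linker histone H1f5 by 2.26 (0.036) and H2bc9 by 2.12 (0.0117), the last to a level under the dim limit. Of 16 histones 8 fell, or 11 when adjusted over the list alone (median -0.80, camera adjusted p = 3.31e-07, adjusted p = 0.448 with an estimated correlation). Over the replication list the median deviation of low arginine replicate 1 was 0.11 against -0.45 and -0.57, and without it 17 members fell, and over the histones it was -0.12 against -0.65 and -0.58. The groups overlapped over the replication list, control replicates 1, 2 and 3 lying at 0.52, 0.33 and 0.08. Within each replicate number the low arginine array lay lower, though the labels do not pair them. Over the replication list control replicate 1 lay above the other controls (median difference 0.40). Without control replicate 2, low arginine replicate 2 or low arginine replicate 3, the count of replication genes was 0, 0 or 1 and that of histones 2, 3 or 3. The calls of the 6 genes named here ended without low arginine replicate 2 (adjusted p = 0.0506 to 0.134) and without control replicate 2 (0.0517 to 0.107). Those of Tk1, Ccne1, H1f5 and H2bc9 also ended without low arginine replicate 3 (0.0542 to 0.131), and that of H1f5 without control replicate 3 (0.0528).

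Targets of the tumour suppressor p53 shifted up slightly. Sesn2 rose by 1.55 (adjusted p = 0.00318), Zmat3 by 1.29 (0.0156) and the ribonucleotide reductase subunit Rrm2b by 0.67 (0.0138), Phlda3 rose, and Ckap2, a spindle protein, fell. Sesn2 also stands in the list of Atf4 targets. Cdkn1a, the p53 target that halts the cell cycle, changed by -0.26 (adjusted p = 0.434), and the G1 cyclin Ccnd3 by -0.24 (0.311). These were 4 rises and 1 fall among 24 members, or 6 and 1 when adjusted over the list alone (median 0.19, camera adjusted p = 0.0454, adjusted p = 0.481 with an estimated correlation). The list call ended without control replicate 2 (adjusted p = 0.0756) or low arginine replicate 1 (0.0913) or 2 (0.0736), and with 0.5 of genes left out as dim (0.0571). There were 8 rises without control replicate 1, 1 without control replicate 2 or low arginine replicate 2, and 2 without low arginine replicate 3. Zmat3 and Rrm2b did not pass without control replicate 2, low arginine replicate 2 or low arginine replicate 3 (adjusted p = 0.0576 to 0.0746), Ckap2 without the first 2 of these (0.0591 and 0.066), and Phlda3 without any single array other than control replicate 1 (0.0784 to 0.138) or after any other scaling or with a trended, robust prior (0.0505 to 0.0562).

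Ribosome biogenesis genes shifted up. Noc3l rose by 1.32 (adjusted p = 0.047), Polr1a, the largest subunit of RNA polymerase I, by 0.93 (0.0421) and Nop14 by 0.90 (0.0282), and Nop58 and Rrs1 rose. These 5 of 46 members passed over all genes, and 41 of 46 had a positive change (median 0.56, camera adjusted p = 2.56e-07, adjusted p = 0.562 with an estimated correlation). Limma passed 0 when adjusted over the list alone, with 21 higher at an unadjusted p below 0.05, and fry gave an adjusted p of 0.22. Control replicate 1 lay above the other controls over this list (median difference 0.88), at the level of the low arginine arrays. Without it 36 members rose, without control replicate 3 it was 1, and without any other single array 0. The calls of the 5 genes all ended without any single array other than control replicate 1 (adjusted p = 0.0581 to 0.162). Median centring ended the calls of Noc3l (adjusted p = 0.0505) and Nop58 (0.0556), 75th percentile centring those of Nop58 (0.061) and Rrs1 (0.0532), quantile normalization that of Rrs1 (0.0568), and averaging the probe sets that of Rrs1 as well (0.0679). With no filter on dim genes Noc3l, Polr1a and Nop58 failed (0.0513 to 0.0593).

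Ribosomal protein genes had a small shift. Rps20 rose by 1.10 (adjusted p = 0.00974), the 1 member of 57 to pass over all genes or when adjusted over the list alone (median 0.08, camera adjusted p = 0.0322, adjusted p = 0.78 with an estimated correlation). Its other, dimmer probe set changed by 0.18. The list call ended without control replicate 1 (median 0.04, adjusted p = 0.461) or low arginine replicate 2 (0.143), after 75th percentile centring (median 0.02, 0.0622) and with array weights (median 0.02, 0.609). The median was 0.13 without control replicate 2 and 0.05 after median centring. Rps20 did not pass without low arginine replicate 2 (adjusted p = 0.0534), and 2 members rose without control replicate 1 or 3.

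Genes of protein folding, oxidative stress, autophagy and cell death were not called shifted by camera. In the endoplasmic reticulum list, Dnajb9 and Sel1l rose, and the chaperone Hsp90b1 and the transcription factor Xbp1 fell. These were 4 of 23 members, or 2 higher and 5 lower when adjusted over the list alone (median -0.16, camera adjusted p = 0.277). Slc7a11 rose and Pgd fell among 14 Nrf2 targets, with the same counts when adjusted over the list alone (median -0.11, camera adjusted p = 0.497). Slc7a11 also stands in the lists of Atf4 targets and amino acid transporters. Gabarapl1 and Gla fell among 33 autophagy and lysosome genes, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.446). Of 20 genes of the Bcl2 family and death receptors, Bcl2l1, an inhibitor of cell death, rose, and Fasl and Bak1 fell, also when adjusted over the list alone (median 0.01, mean -0.06, camera upward with adjusted p = 0.913). Without control replicate 3 the endoplasmic reticulum list passed camera as shifted down (adjusted p = 0.0236), and control replicate 1 lay above the other controls over it (median difference 0.74). Without control replicate 1 its median was 0.08 and camera's direction upward (adjusted p = 0.471), and with array weights the median was 0.09. It was -0.33 without control replicate 2 and -0.39 without control replicate 3. Apart from Gabarapl1 and Fasl, each of these genes lost its call without low arginine replicate 2 (adjusted p = 0.0511 to 0.124) and without control replicate 2 (0.0572 to 0.124). Apart from Slc7a11 and Gla, the same genes also failed without low arginine replicate 3 (0.0609 to 0.156), as did Sel1l, Hsp90b1, Xbp1, Pgd, Bcl2l1 and Bak1 without low arginine replicate 1 (0.0544 to 0.129) and Hsp90b1 and Bcl2l1 without control replicate 3 (0.0503 and 0.0667), while Hsp90b1 and Bak1 failed with no filter on dim genes (0.0555 and 0.0567). Without control replicate 1, 5 endoplasmic reticulum genes rose and 4 fell, 2 Nrf2 targets rose and 2 fell, 4 autophagy genes fell and 2 genes of the Bcl2 family and death receptors rose. Leaving out 1 array at a time put the autophagy median between -0.10 and -0.02. That of the Bcl2 family and death receptors then lay between -0.05 and 0.12.

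Type I interferon-stimulated genes shifted up. Rtp4 rose by 2.06 (adjusted p = 0.00852), the antiviral gene Ifit1 by 1.65 (0.044) and the transcription factor Irf7 by 1.35 (0.0114), and Irf9 and Ifi35 rose. These were 5 of 26 members, or 13 higher and 1 lower (Dhx58) when adjusted over the list alone (median 0.54, camera adjusted p = 6.07e-05, adjusted p = 0.562 with an estimated correlation). Over these genes control replicate 1 lay above the other controls (median difference 0.50), and the arrays of both groups overlapped in their median deviations. Within each replicate number the low arginine array lay above the control array (0.58 against 0.03, 0.26 against -0.39 and -0.12 against -0.56). The labels do not pair these arrays. There were 13 rises without control replicate 1, 1 without control replicate 2 or low arginine replicate 2, and 3 without low arginine replicate 1. Without low arginine replicate 2 or control replicate 2, Ifit1, Irf7, Irf9 and Ifi35 did not pass (adjusted p = 0.0527 to 0.151). Ifit1 and Ifi35 also failed without low arginine replicate 1 (0.122 and 0.0606), Ifit1 without control replicate 3 (0.107), and Irf9 and Ifi35 without low arginine replicate 3 (0.055 and 0.0587), while Ifit1 failed after quantile normalization (0.0522) or with no filter on dim genes (0.0563) and Ifi35 with its probe sets averaged (0.0542).

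**Figure D3:**
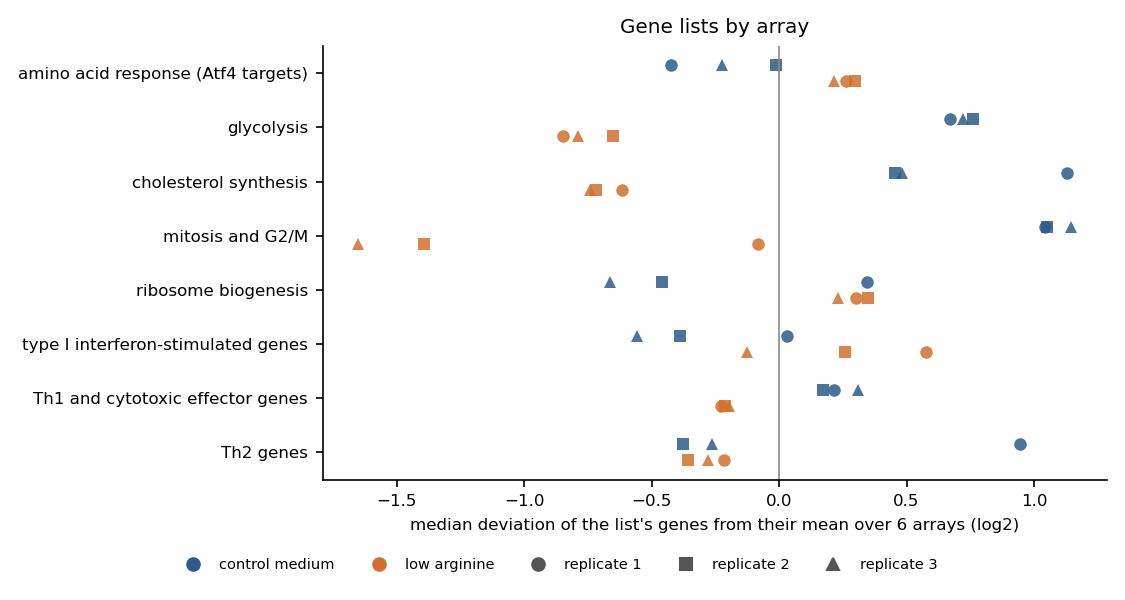
Median deviation of the genes of 8 lists from their mean over the 6 arrays (log2, horizontal axis) in control medium (blue) and low arginine (orange); each point is 1 array and the marker gives the replicate number. Control replicate 1 lay apart from the other controls over ribosome biogenesis, cholesterol synthesis and Th2 genes, and low arginine replicate 1 apart from its group over mitosis genes (-0.08).

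Genes of the T cell receptor were at high levels in both groups. Cd3e, a chain of the receptor complex, was at 10.8 ± 0.04 in control medium and 10.9 ± 0.08 in low arginine (SD, n = 3; limma adjusted p = 0.597), and Cd4 changed by -0.24 (0.29). Of 17 members of the receptor and proximal signalling list only Themis, a signalling protein of the receptor, passed, and it fell, also when adjusted over the list alone (median -0.04, camera adjusted p = 0.517). Without control replicate 1, 2 members fell. Cd247 and Lck were not analysed here.

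Activation genes went both ways. Il2, Cd69 and Egr3 rose, and Tnfrsf9, Nfil3 and Hif1a fell, among 25 members (6 higher and 4 lower when adjusted over the list alone; median 0.07, camera adjusted p = 0.775). Il2ra, a receptor chain for Il2, changed by 0.02 (adjusted p = 0.952) at a level of 10.8 in both groups, and Myc by 0.24 (0.258). Tnfrsf9, Nfil3 and Il2 stayed past the threshold without any single array. Cd69 did not pass without control replicate 2, low arginine replicate 1 or low arginine replicate 2 (adjusted p = 0.0563 to 0.0818). Hif1a failed without control replicate 2 or any single low arginine array (0.0995 to 0.133), and Egr3 without any single array other than low arginine replicate 1 (0.0572 to 0.172) and after each other scaling, with no filter on dim genes or with a trended, robust prior (0.0535 to 0.0724). There were 5 rises without control replicate 1, 1 without control replicate 2 or low arginine replicate 2, and 5 falls without control replicate 3.

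Genes of naive and quiescent T cells shifted up. The interleukin 6 receptor gene Il6ra rose by 1.94 (adjusted p = 0.00474), S1pr1, needed for exit from lymphoid organs, by 1.93 (0.00958) and the transcription factor Lef1 by 0.86 (0.0036). Foxo1 and Foxp1 rose, and Il7r, the receptor for a survival cytokine, fell. These were 5 rises and 1 fall among 22 members, or 6 and 1 when adjusted over the list alone (median 0.24, camera adjusted p = 0.0149, adjusted p = 0.59 with an estimated correlation). Control replicate 1 lay below the other controls over this list (median difference -0.55), and the list call ended without it (median 0.09, adjusted p = 0.36), where 3 members fell, and with array weights (0.147). There were 3 rises without control replicate 2, low arginine replicate 2 or low arginine replicate 3, where Foxo1 and Foxp1 did not pass (adjusted p = 0.0521 to 0.0664). Il7r did not pass without low arginine replicate 2 or 3 (0.0529 and 0.0516), nor Foxo1 with its probe sets averaged (0.121).

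Genes of inhibitory receptors and dysfunction were not called shifted. The ligand gene Cd274 rose, and Ctla4, Tigit and Entpd1 fell, among 17 members, or 4 higher and 3 lower when adjusted over the list alone. The median change was 0.24, the mean -0.02 and camera's direction upward (adjusted p = 0.774). The median was 0.10 without low arginine replicate 3. These 4 genes stayed past the threshold without any single array. Over these genes control replicate 1 lay below the other controls (median difference -0.33), and without it 5 members rose and 6 fell, with camera's direction downward (adjusted p = 0.851).

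Th1 and cytotoxic effector genes shifted down. Gzmb, the granzyme of cytotoxic granules, went from 10.8 ± 0.18 to 7.10 ± 1.12 (SD, n = 3; limma adjusted p = 0.00534). Il12rb2, a chain of the interleukin 12 receptor, fell by 2.20 (adjusted p = 0.00606) and Gzmc by 1.94 (0.00189), to a level under the dim limit. The cytokine gene Tnf and the chemokine genes Ccl3 and Ccl4 rose, while Ifng changed by -0.03 (adjusted p = 0.957) at a low level of 3.23 in control medium. Of 22 members 10 fell and 3 rose, or 11 and 5 when adjusted over the list alone (median -0.57, camera adjusted p = 0.00626, adjusted p = 0.448 with an estimated correlation). CD8 and NK cell markers shifted down beside it (median -0.61, camera adjusted p = 0.0412, adjusted p = 0.481 with an estimated correlation), Cd8b1 among them changing by -0.66 (0.0632). The call of the Th1 list ended with array weights (adjusted p = 0.0709). The count of falls was 6 without control replicate 2 or low arginine replicate 2 and 5 without low arginine replicate 1. Ccl3 did not pass without any single array other than control replicate 1 (adjusted p = 0.059 to 0.133), nor Ccl4 without control replicate 2 or low arginine replicate 3 (0.0916 and 0.0717), which left Tnf as the only rise without either of these.

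Th2 genes were not called shifted, with 1 of 12 members past the threshold, the cytokine gene Il24, which fell. Adjusted over the list alone, Csf2 was higher and Il24 lower (median -0.46, camera adjusted p = 0.517). Control replicate 1 lay far above the other controls over this list (median difference 1.69), and without it the median was -0.02 and camera's direction upward (adjusted p = 0.834). It was -0.26 with no filter on dim genes or with 0.5 of genes left out as dim, and -0.04 with array weights. Il24 did not pass without control replicate 2 or any single low arginine array (adjusted p = 0.0597 to 0.135), while 3 members rose without control replicate 1 and 1 without low arginine replicate 3.

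Th17 and Tfh genes shifted up. Bcl6, the transcription factor of follicular helper cells, rose by 1.42 (adjusted p = 0.0462), the cytokine gene Il17a by 1.19 (0.0197) and the receptor gene Slamf6 by 0.61 (0.0399). These were 3 of 14 members, also when adjusted over the list alone (median 0.41, camera adjusted p = 0.0322, adjusted p = 0.481 with an estimated correlation). The median difference of control replicate 1 from the other controls over this list was -0.48, and the list call ended without it (adjusted p = 0.307) and with array weights (0.147). The other probe set of Slamf6 changed by 0.10, and with the probe sets averaged Slamf6 did not pass (adjusted p = 0.2), nor with 75th percentile centring (0.0526). Bcl6 and Slamf6 did not pass without control replicate 2 or any single low arginine array (adjusted p = 0.105 to 0.16), nor Il17a without low arginine replicate 2 or 3 (0.0879 and 0.0837), and Bcl6 failed with no filter on dim genes (0.0584). The count was 1 without control replicate 2 or low arginine replicate 1 and 0 without low arginine replicate 2 or 3.

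Regulatory T cell genes shifted up. Foxp3, the transcription factor that defines these cells, went from 7.20 ± 0.35 to 9.18 ± 0.69 (SD, n = 3; limma adjusted p = 0.0117). Nrp1 rose by 1.85 (adjusted p = 0.00669) and Rgs16 by 1.80 (0.0142), and Gpr83 rose. These were 4 of 15 members, or 6 when adjusted over the list alone (median 0.21, camera adjusted p = 0.0119, adjusted p = 0.481 with an estimated correlation). Control replicate 1 lay below the other controls over this list (median difference -0.20), and the list call ended without it (adjusted p = 0.0829) and with array weights (0.0812). Its median was 0.42 without low arginine replicate 1, 0.06 without low arginine replicate 3, 0.32 with 0.5 of genes left out as dim and 0.08 with array weights. Without control replicate 2 the count was 2, and Foxp3 (adjusted p = 0.0591) and Rgs16 (0.0702) did not pass. Rgs16 also failed without low arginine replicate 2 (0.0694) or 3 (0.0629).

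Markers of other cell types that a co-culture can leave behind were mostly dim. Some were bright, among them Cd209a (mean 7.97 over all arrays) and Ighm (7.84), each in its brightest probe set. Limma passed 0 of 6 B cell, 0 of 8 macrophage and monocyte, 0 of 8 neutrophil and 0 of 5 erythroid markers, over all genes and when adjusted over the list alone. At an unadjusted p below 0.05 there was 1 among them, the macrophage gene Ctss, at 6.60 ± 0.44 and 7.34 ± 0.11 (SD, n = 3; limma adjusted p = 0.0604), and fry passed none of these lists. The list medians were -0.00 for B cells (mean 0.01, camera upward with adjusted p = 0.986), 0.02 for macrophages (0.673), -0.02 for neutrophils (0.758) and -0.15 for erythroid cells (0.45). The brightest B cell marker was Bank1 at 3.24 in control medium (change -0.05), and Blk had the largest change (0.28). Cxcr2 (-0.09) and Mpo (-0.22) took these places among neutrophil markers, and Ermap (0.06) and Car1 (-0.99, adjusted p = 0.232) among erythroid markers, with control levels of 2.82 to 3.34. Over the erythroid list control replicate 1 lay above the other controls (median difference 0.41). Ctss passed without control replicate 1 (adjusted p = 0.0254) or 3 (0.0391), and with array weights (0.00321).

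Among dendritic cell and MHC class II genes, H2-Ab1, a chain of the class II molecule, went from 7.21 ± 0.46 to 4.15 ± 0.07 (SD, n = 3; limma adjusted p = 6.02e-04). H2-Eb1, a chain of another class II molecule chosen after its value was seen, changed by 0.02. Cd83 rose, and the brightest member, Cd209a, changed by 0.19 (adjusted p = 0.584), with -0.12 in its other probe set. These were 1 rise and 1 fall among 11 members, also when adjusted over the list alone (median 0.11, mean -0.13, camera upward with adjusted p = 0.8). Over the alternatives the median lay between 0.02 and 0.19, and camera's direction was downward without control replicate 1 (adjusted p = 0.851). Cd83 did not pass without control replicate 2 or any single low arginine array (adjusted p = 0.0947 to 0.126), nor after quantile normalization (0.0545).

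CD8 and NK cell markers shifted down. Gzma, a granzyme, fell by 1.68 (adjusted p = 0.0177), to a level under the dim limit, and the receptor gene Klrk1 fell by 1.04 (0.0134). The brightest member, the CD8 chain gene Cd8b1, changed by -0.66 (adjusted p = 0.0632), from 6.90 ± 0.34 to 6.24 ± 0.21 (SD, n = 3). Of 9 members 2 fell, or 3 when adjusted over the list alone, where Eomes was higher (median -0.61, camera adjusted p = 0.0412, adjusted p = 0.481 with an estimated correlation). Gzma and Eomes also stand in T cell lists. The list call ended without control replicate 3 (median -0.38, adjusted p = 0.0685) or low arginine replicate 1 (0.108), after 75th percentile centring (0.0564), with no filter on dim genes (median -0.29, 0.0504) and with array weights (0.0812). Without control replicate 1, 5 members fell, among them Cd8b1 (adjusted p = 0.00588), which also passed with array weights (0.00114). Gzma did not pass without any single low arginine array (0.0511 to 0.0777), nor Klrk1 without control replicate 2 or low arginine replicate 3 (0.065 and 0.0638), which left 1 fall without control replicate 2 or low arginine replicate 1 or 2 and 0 without low arginine replicate 3.

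Plasma cell markers were not called shifted by camera (median -0.40, adjusted p = 0.0581). Prdm1, a transcription factor of plasma cells and effector T cells, fell by 1.36 (adjusted p = 0.00474) and Xbp1 by 0.76 (0.0157), and Ighm fell, 3 of 6 members, also when adjusted over the list alone. Fry passed the list as down (adjusted p = 0.00464), as did camera without control replicate 2 (0.0354) and with 0.5 of genes left out as dim (0.049). In that last setting the median was -0.76, while it was -0.11 with the probe sets averaged and -0.03 with no filter on dim genes. Xbp1 did not pass without control replicate 2 or any single low arginine array (adjusted p = 0.0544 to 0.0754), nor Ighm without low arginine replicate 3 (0.0519), where the count was 1. With its probe sets averaged Ighm did not pass (adjusted p = 0.412).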

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

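The tests of the 3 patterns weighed here were chosen only after the results they bear on had been seen. Probe sets outside the comparison carried signal. Among those with several gene symbols, 28 were higher and 52 lower in low arginine (limma over all probe sets, adjusted p below 0.05). Among those with no symbol, 190 were higher and 105 lower. For scale, the probe sets with 1 symbol gave 331 and 579 in that fit.

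Glycolysis fell in 17 of 18 members, with a median of -1.48. Quantile normalization and both centrings changed the calls of 239 to 394 genes and left the median of this list at -1.48 or lower. The deposited arrays were already normalised, and the centrings moved the difference between the groups by only 0.0357 (median) and 0.0599 (75th percentile). Such small shifts could not have removed a fall of this size, so these settings cannot decide whether the authors' own normalization played a part. A change shared by all genes, which normalization removes, stays open. Lower activity of the hypoxia response may account for part of the fall of glycolysis. Hypoxia-induced genes outside glycolysis had a median change of -1.54, with Egln3 down by 3.47 and Ak4 by 2.92 among them. Within the controls the hypoxia-induced genes and glycolysis did not move together. Control replicate 1 lay below both other controls in all these genes but Egln3, Ak4, Pgm2, Wsb1 and Cited2 (Gbe1 at 6.89 against 8.41 and 8.36). Over the glycolysis list that array was not lower (median difference 0.11). Direct effects of arginine on these genes stay open and untested. The test was run on the same arrays in which the fall was seen, so the link is a hypothesis.

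Foxp3 rose from 7.20 to 9.18. A larger share of regulatory T cells among the harvested cells could produce this, as could more Foxp3 per cell. If the share alone had grown, genes restricted to these cells would rise by about as much. The 95% interval lay under that of Foxp3 (from 1.21) for 2 of the 6 other restricted genes (a larger share of regulatory T cells). These were Ikzf2, which missed it narrowly (upper bound 1.18), and Itgae (upper bound 0.72). Itgae had a control level of 3.31, within 1 log2 of the dim limit. The intervals of Nrp1, Gpr83, Lrrc32 and Ikzf4 reached that of Foxp3. The share and the level per cell cannot be told apart here, because other T cells also express several of these genes.

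Control replicate 1 stood apart from the other controls, with 498 genes over 1 log2 from their mean against 29 and 165 for control replicates 2 and 3, and Il13 at 8.40 against 5.45 and 4.38. An exchange with a low arginine array is argued against, since over the glycolysis and mitosis lists it lay at most 0.036 of the way from the other controls to low arginine. Carry-over of the cell types listed cannot be told apart from other causes, since most of the 7 such lists lay near the floor. Their median control levels lay within 1 log2 of the dim limit. The largest median deviation among the 7 lists was 0.406 (erythroid markers). Markers of mast cells and basophils were not among the lists, and Cpa3, a mast cell gene, was at 8.48 against 6.82 and 6.37 in the other controls, while Kit was lower (4.09 against 5.33 and 5.64). A shared origin of both replicate 1 cultures stays open too. The deviations of both arrays correlated at 0.355 over the 498 genes and at 0.121 over all genes. Over the 498 genes their median size was 1.22 in control medium, with a median of 0.07 in the same direction in low arginine. Mean Y-linked levels were 5.73 in control replicate 1 and 5.55 in low arginine replicate 1, against 4.09 and 2.40 in the other controls. The labels state neither the mice nor their sex, so a difference between mice was not tested.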

How the results depend on the processing

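All alternatives here were planned, apart from the tests of the added gene lists. No result changed direction past its threshold. Quantile normalization, the centrings, the filters, the mean of probe sets and the trended, robust prior kept all counts within 1.5 times the values reported, and shared 1565 to 1755 of the 1799 genes, with none of opposite sign. Camera's calls were 9 to 11 lists up and 7 to 9 down in these settings. With array weights 5514 genes passed (2777 higher, 2737 lower), all 1799 among them, and 5 lists shifted up. Leaving out 1 array gave 500 to 3325 genes, 161 to 1626 higher and 338 to 1699 lower, 323 to 783 changed at least 2-fold, 7 to 11 lists up and 7 to 9 down. The highest count came without control replicate 1, the array that stands apart. All of these fits had 5 arrays, and why their counts differ was not tested. With an estimated correlation camera called 0 lists up and 0 down, 3 lists lying at an unadjusted p below 0.05, and fry called 2 up and 7 down.

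Of 141 named genes tested, 116 passed, and 54 of these passed without any single array. The calls that ended numbered 1, 55 and 17 without control replicates 1, 2 and 3, and 31, 55 and 49 without low arginine replicates 1, 2 and 3. The other settings ended 0 to 11. Among list calls the replicate block ended that of the p53 targets (adjusted p = 0.0578). With the replicate block Cd8b1 passed (adjusted p = 0.0312), while the calls of Yars, Eprs, Noc3l, Nop58, Bcl6, Slamf6, Oaz1, Sel1l, Hsp90b1, Hif1a and Ccl3 ended (0.0501 to 0.0749).

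The labels give both groups the same replicate numbers without saying that a number marks a shared mouse or day. Deviations from the group means correlated at 0.121, 0.0588 and 0.141 for equal numbers and at -0.134 to 0.0426 for different ones, and 6 of 6 arrays correlated best with their own number, a hint from the data rather than the design. Mean Y-linked levels differed by at most 0.287 between arrays of equal number and by at least 1.41 between different numbers. The main fit leaves such a pairing out. With the replicate block 1568 genes passed (632 higher, 936 lower, 606 at least 2-fold), 1372 of them among the 1799, with 10 lists up and 8 down. In that fit 12 interferon-stimulated genes rose and 16 replication genes fell, against 5 and 8 in the main fit. The rises were fewer, 1 against 3, both among the aminoacyl-tRNA synthetases and among the Th17 and Tfh genes.

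There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 1799 genes (767 higher, 1032 lower, 580 at least 2-fold) and the highest other 0 in each, by limma, with at most 869 genes at an unadjusted p below 0.05. Every other split mixes both media in each part, which puts the difference between the media into the residual. Low gene counts were therefore favoured in advance there and do not measure what chance would give. As a split has no direction of its own, the larger of its up and down counts was set against the real value. For the gene counts 1 split, the real one, reached that value, as for the 11 lists up (highest other 9). Counted this way 4 splits, the real one included, reached the 8 lists down (highest other 9).

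A correction for background was not possible without the scanner files; not run. Without signals over background, a change has no firm size where a group lay under the dim limit of 2.48 (Il2, Gzmc, Gzma, H2bc9, Car1) or within 1 log2 above it (Scd1, Fads2, Bnip3, Mt3, Slc7a11, Cdc25c, Aldh1l2, Klrk1, Gabarapl1, Nrp1, Itgae, Il17a, Ccl3, Ccl4, Csf2, Ifng, Arg1 and the B cell, neutrophil and erythroid markers named).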

Other observations

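The tests of the 6 added gene lists and of Y-linked levels were chosen after the results had been seen, so their p values rest on genes already known to move, and the genes named from them were chosen after their values were seen. Hypoxia-induced genes outside glycolysis fell in 19 of 25 members, or 24 when adjusted over the list alone, with a median of -1.54 (camera p = 3.83e-22, p = 0.0237 with an estimated correlation). Bnip3 fell by 4.11, the oxygen sensor Egln3 by 3.47 and the adenylate kinase Ak4 by 2.92. Genes of fatty acid synthesis and desaturation fell in 7 of 15 members, or 9 when adjusted over the list alone, with a median of -0.57 (camera p = 7.07e-08, p = 0.0697 with an estimated correlation). Besides Fads2 and Scd1 they included the elongase Elovl6, which fell by 1.94.

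Of 5 metallothionein and zinc genes, Mt1, Mt2, Mt3 and the zinc importer Slc39a10 fell, over all genes and when adjusted over the list alone (median -1.03, camera p = 3.05e-05, p = 0.0131 with an estimated correlation). Mt3 fell by 0.59 to the dim limit and did not pass without any single array other than control replicate 1 (adjusted p = 0.0627 to 0.167) or with no filter on dim genes (0.0533), nor did Slc39a10 without control replicate 2 (0.0556). Of 13 circadian clock genes, Nr1d2 rose by 1.76 and Cry1 by 0.70, also when adjusted over the list alone (median 0.16, or 0.07 without low arginine replicate 3, camera p = 0.102, p = 0.444 with an estimated correlation). Nr1d2 did not pass without control replicate 2 or low arginine replicate 3 (adjusted p = 0.0543 and 0.0507), nor Cry1 without control replicate 2 or low arginine replicate 2 or 3 (0.0757 to 0.0891). Of 7 genes restricted to regulatory T cells, Foxp3, Nrp1 and Gpr83 rose, or 5 when adjusted over the list alone (median 0.97, camera p = 1.37e-04, p = 0.137 with an estimated correlation).

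The mean of 3 Y-linked genes was 5.73, 4.09 and 2.40 in control replicates 1, 2 and 3 and 5.55, 4.15 and 2.11 in the low arginine replicates of those numbers. Limma passed 0 of the 3 between the groups, and 0 at an unadjusted p below 0.05, and neither camera nor fry called them. Same-numbered arrays differed by at most 0.287, while arrays of different numbers differed by at least 1.41. A candidate explanation is that arrays of 1 number hold cells of the same mice, male, female or mixed, which the labels do not state. A test of a larger share of resting cells as the source of the Foxp3 rise was set aside as void after it was run, because naive T cell genes (median 0.24) start high enough to hide a small share.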
